A study of Mus musculus with 4 samples.

How the data were processed

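Liver RNA of male C57BL/6J mice was profiled on 4 biotin-labelled whole-transcript arrays, 1 for each of 4 infusion groups. Per the labels' protocols, the mice had eaten a semi-synthetic palm oil diet for 6 weeks and carried a permanent catheter in the cecum, the pouch where the large intestine begins. After a short morning fast, conscious mice received saline or the sodium salt of a carbon-13 labelled short-chain fatty acid through the catheter. Each acid was given at 0.3 M and 0.2 ml/h, a rate of 2.4 mmol/h/kg, and the livers were taken after 6 h. The sodium content of the saline is not given in the sources used here, so the sodium load was matched between the acids and is not known to match the control.

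Per the labels, equal amounts of RNA (500 ng per mouse) were pooled within each group before hybridization. The control, acetate and propionate pools held RNA of 6 mice each and the butyrate pool of 4 mice. Livers with an RNA integrity number above 8 were used, and 100 ng of pooled RNA entered cDNA synthesis, per the labels' protocols.

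The deposited values are log2 expression values per probe set. RMA, a method that corrects background, makes the arrays' distributions alike and summarises probes into probe sets, is named in the submitters' processing notes. Its version and settings are not given in the sources used here. The values fit that scale: the medians of the 4 arrays lay between 5.11 and 5.12, with a lowest value of 1.60 and a highest of 13.7. Nothing was centred by gene, so levels and ratios could both be read. Because the distributions had been made alike, a shift of all genes in one pool could not be seen.

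Probe sets were named from GEO's platform annotation. Of 35556 probe sets, 21218 had 1 gene symbol, 1881 had several and 12457 had none there. Of those with 1 symbol, 21185 matched a RefSeq gene table (assembly GRCm38.p6, used for names only) by Entrez ID, 33 did not, and 0 symbols changed. The build of the array's design is not given in the sources used here, so no coordinates are printed. Probe sets of the same symbol were averaged, which gave 18820 genes, 1386 of them with more than 1 probe set. Probe sets with several symbols or none entered no comparison of genes. Short probes can cross-hybridise between close paralogs, so values of Cyp2b, Cyp4a, Acot, Gstm, Orm, Clec4a, Sprr2a, myosin heavy chain, tubulin and Mup genes are uncertain as to the member.

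With 1 array per group no spread between replicates can be estimated, so no p-value, standard error or standard deviation between replicates is given. Each comparison was the log2 ratio of 2 arrays. There were 6: each acid against the control, and the acids against one another. A gene was counted as higher or lower at a ratio of at least 1.5-fold (0.58 on the log2 scale). Counts were taken over the 9410 genes whose mean over the 4 arrays lay at or above the median of all genes' means, a level floor of 5.55. The number of arrays limits the precision of the values.

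Before the data were examined, 44 gene lists of 703 different genes were fixed for metabolism, signalling, cell types and quality. They were fatty acid synthesis, cholesterol synthesis, gluconeogenesis, glycolysis and glycogen, fatty acid oxidation, PPARalpha targets, ketone body metabolism, propionate catabolism, acyl-CoA formation, short-chain fatty acid transport and receptors, the TCA cycle, the respiratory chain, bile acids, lipoproteins, the urea cycle, branched-chain amino acids, xenobiotic metabolism, NRF2 targets, the unfolded protein response, heat shock proteins, the acute phase, glucocorticoid targets, immediate early genes, the circadian clock, the interferon response, male-biased and female-biased genes, the cell cycle, histone deacetylases, genes that rise when these enzymes are inhibited, ribosomal proteins, and markers of hepatocytes, both liver zones, Kupffer cells, neutrophils and monocytes, lymphocytes, endothelium, stellate cells, cholangiocytes, red cells, pancreatic acini, adipocytes and skeletal muscle. The median log2 ratio of each list, whatever its members' levels, was placed among those of 10000 random lists of the same size. The random lists were matched on mean expression in 20 bins. A list was said to stand apart at or below percentile 2.5 or at or above percentile 97.5. This describes the arrays and is no p-value. Genes of a shared pathway or cell type vary together more than random genes do, so the 5% of lists that chance places outside is a lower guide.

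The genes named were chosen by a rule set beforehand. It takes the 12 highest and 12 lowest ratios of each acid against control, the 6 highest and 6 lowest of each pair of acids and, on each side, the 8 genes with the largest smallest ratio over all 3 acids. It covers genes at or above the floor with exactly 1 symbol, without predicted, olfactory, vomeronasal, microRNA, small nuclear and accession-like names. It adds 2 to 5 members per list in order of absolute ratio, and genes close to the subject, among them Fgf21, Cpt1a, Pck1, G6pc, Fasn, Srebf1, Acss2, Cyp7a1, Ppargc1a, Ffar2, Ffar3 and histone deacetylase genes. Symbols of 23 gene families and of tissue markers outside this rule were looked at after the data had been seen, and appear in the closing part.

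All 3 acids were compared with the same control pool, so chance values of that pool enter each ratio. The correlation and covariance of ratios across genes are therefore given beside those of 100 simulations of unchanged groups that share a control, with noise by expression level taken from the ratio of the propionate and acetate pools, and overlaps beside the number that independent lists would give. Genes of families not used by liver (1277 olfactory, vomeronasal, taste receptor, keratin-associated and defensin genes) served as a yardstick for the spread at background level.

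The size rule was tested on simulated array pairs with known changes, on 9410 genes with 200 changed in each of 20 simulated pairs of an acid pool and the control pool. The rule found 53.0% of genes changed 1.5-fold, 99.5% of those changed 2-fold and 100% of those changed 4-fold. On average 5.05 unchanged genes per pair passed it, a share of 0.055%. The noise was that of propionate against acetate, the comparison with the smallest SD of ratios (0.15), so this number is a lower guide. In the measured arrays 0.47%, 0.70% and 0.55% of the genes of families not used by liver passed with acetate, propionate and butyrate. The list percentile was tested on 18820 genes of the simulated pairs. Lists of 15 genes shifted by 0.2 were found in 98.5% of cases and unchanged ones in 5.5%.

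Alternatives were size rules of 1.3-fold and 2-fold, no floor or a floor at the upper quartile, cyclic loess or quantile normalization on top of the deposited values, the highest probe set per symbol, the mean of a list, its members above the floor, unmatched random lists, and the mean of the other 3 pools in place of the control. A count without the genes of the muscle, pancreas, intestine, blood cell and adipocyte lists was added after the data had been seen. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used, and R 4.3.3 with limma 3.58.1 for the added normalizations.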

Results

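The study infused short-chain fatty acids, products of bacterial fermentation in the large intestine, into the cecum of mice and asked how gene expression in the liver compared with that after saline. Acetate, propionate and butyrate, which differ in carbon chain length, were given at the same molar rate for 6 h. Liver RNA of 22 mice was combined into 4 pools, of 6 control, 6 acetate, 6 propionate and 4 butyrate mice, and each pool was measured on 1 array. There were no replicates, so no difference given here has a replicate check, and every ratio compares 2 pools. The butyrate pool rested on fewer mice, so a single liver weighed more in it.

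The pools were close to one another. Across the 9410 genes at or above the level floor, Pearson's r between pairs of arrays ran from 0.990 to 0.996 (genes are not independent replicates). Of the 9410 genes at or above the level floor, 90.1%, 89.8% and 91.4% lay within 1.2-fold of the control pool after acetate, propionate and butyrate. At least 1.5-fold higher than control were 59 genes with acetate, 66 with propionate and 71 with butyrate. At least 1.5-fold lower were 48, 38 and 34 genes. Among 1277 genes of families not used by liver, 6, 9 and 7 differed by 1.5-fold, and their log2 ratios had an SD across genes of 0.17, 0.20 and 0.18. Of the 43 fixed lists with at least 5 measured members, 14 stood apart with acetate, 11 with propionate and 16 with butyrate. Lists of random genes would give 2.15. That is a lower guide, because genes of a shared pathway or cell type vary together and some lists share members. A ratio with a level below the floor on either side is a ratio to a value near background, so its size and rank are not exact; genes chosen by rank to which this applies are named with each comparison.

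In the acetate pool, Cyp2b9, a cytochrome P450 of the liver that is female-biased in mice, was 5.79-fold above control (5.45 in control and 7.99 with acetate on the log2 scale). The surface protein gene Ly6d was 3.90-fold higher, the mitochondrial acyl-CoA thioesterase Acot2 2.64-fold and the glutathione transferase Gstm3 2.47-fold. Also among the 12 highest were D17H6S56E-5 (log2 ratio 1.34), the endoplasmic reticulum degradation factor Derl3 (2.30-fold), the tubulin Tuba8 (1.13), the mitotic cyclin Ccnb2 (1.13), the guanylin receptor Gucy2c (1.12), the matrix genes Dpt (1.07) and Mmp2 (1.03), and the retinol dehydrogenase Dhrs9 (1.03). The lowest ratios were those of the neutrophil granule gene Ngp (-1.39), the trefoil peptide Tff2 (-1.14) and genes of the exocrine pancreas, namely Pnliprp2 (-1.12), Sycn (-1.11), Cela1 (2.15-fold lower), Pnliprp1 (-0.97), Cela3b (-0.95) and Prss2 (-0.85). Moxd1 (-1.03), the platelet chemokine Ppbp (-1.02), the antisense gene Hnf4aos (-0.99) and the acute-phase glycoprotein Orm2 (-0.96) completed the 12. Cyp2b9, Gucy2c and Dhrs9 lay below the floor in the control pool, and Ngp and Tff2 in the acetate pool.

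Among metabolic lists, targets of the fatty acid receptor PPARalpha were higher with acetate. Of 19 measured members, 15 lay above control and 2 by at least 1.5-fold, with a median log2 ratio of 0.19 (above all 10000 random lists). After Acot2, the largest ratios were those of Pdk4 (0.68), Cd36 (0.58), Acot1 (0.56) and the peroxisomal oxidation enzyme Ehhadh (0.46). Genes of the TCA cycle and pyruvate dehydrogenase had a median of 0.075 (percentile 99.8), with 16 of 21 members above control. Pdk4 had the largest ratio there too, followed by Pdk1 (-0.31) and Mdh2 (0.18), and both Pdk genes encode kinases that switch pyruvate dehydrogenase off. The 6 measured ketone body genes were all above control, by a median of 0.12 (percentile 98.0), led by Bdh2 (0.15) and Slc16a1 (0.14). Against unmatched random lists the TCA and ketone body lists no longer stood apart, and the ketone body list also lost its place with cyclic loess, with its mean and with members above the floor.

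Targets of NRF2, the regulator of the antioxidant response, had the highest list median with acetate, 0.31 (above all 10000 random lists), with 10 of 12 members above control. Gstm3 led, followed by the cystine transporter Slc7a11 (0.68), whose level lay below the floor in both pools, the glutathione synthesis enzyme Gclc (0.58) and Nqo1 (0.51), below the floor in control, while Hmox1 was lower (-0.48). Heat shock genes had a median of 0.16 (percentile 99.99), with 11 of 12 above control, among them Hsph1 (0.53) and Hspb1 (0.45). Glucocorticoid targets (0.19, above all 10000 random lists) and immediate early genes (0.15, percentile 99.9) were higher as well. Examples were Pdk4, Cdkn1a (0.57) and Sgk1 (0.45) in the former and Nr4a1 (1.03) and Klf6 (0.91) in the latter. Acute-phase genes were lower by a small amount, with 19 of 22 members below control and a median of -0.063 (percentile 0.14). Orm2 and Orm3 (-0.83) passed 1.5-fold, and the list did not stand apart from unmatched random lists.

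Cell-type markers also differed in the acetate pool. Neutrophil and monocyte markers were lower (median -0.22, 10 of 12 below control, percentile 0.03), with S100a8 at -0.45 and S100a9 at -0.44 after Ngp. All 3 lay below the floor in the acetate pool, and 5 of the 12 markers had mean levels at or above it. Kupffer cell markers, of the liver's resident macrophages, had a median of -0.15 (percentile 0.01), but their mean was -0.053, which did not stand apart. Their largest ratios went both ways, with Lyz2 at 0.43, Cd68 at 0.27 and Timd4 at -0.26. Stellate cell and fibroblast markers were higher in 14 of 15 cases (median 0.18, above all 10000 random lists), led by the collagens Col3a1 (0.72) and Col1a1 (0.66). Hepatocyte markers had a median of 0.0031.

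In the propionate pool Cyp2b9 was again the highest gene, 7.07-fold above control. Gucy2c (1.19), Ly6d (2.14-fold), Tuba8 (1.06), Acot2 (1.02), Gstm3 (0.91) and D17H6S56E-5 (0.90) stood among the 12 highest with both acids. The others with propionate were Tmc3 (1.43), the macrophage transcription factor Spic (1.27), the macrophage receptors Clec4n (0.98) and Marco (0.98), and the neutrophil-attracting chemokine Cxcl1 (0.91). Cyp2b9, Gucy2c and Tmc3 lay below the floor in the control pool. The lowest were Moxd1 (-1.32), Dmbt1 (-1.12), Btbd19 (-1.09), Tff2 (-0.92), Zyg11a (-0.74), the pancreatic genes Pnliprp2 (-0.86) and Cela1 (-0.76), and the hexosamine enzyme Gfpt1 (-0.79). The remaining 4 act in protein folding and degradation of the endoplasmic reticulum, namely Creld2 (-1.18), Sdf2l1 (-0.96), Manf (-0.84) and Syvn1 (-0.79). Against the mean of the other 3 pools, which holds the acetate pool, Ly6d, Acot2, Gstm3, Cxcl1, D17H6S56E-5, Sdf2l1, Tff2, Pnliprp2, Manf, Syvn1, Cela1 and Zyg11a lay under 1.5-fold with propionate, as did Gucy2c, Moxd1, Cela3b and Prss2 with acetate.

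Unfolded protein response genes were lower with propionate, with 13 of 19 members below control, 4 of them by at least 1.5-fold, and a median of -0.22 (below all 10000 random lists). Hyou1 (-0.74) and the chaperone Hspa5 (-0.58) followed Creld2, Sdf2l1 and Manf. The list was below the random lists with acetate too (median -0.15, 13 of 19 below control), where Derl3 and Atf3 (0.57) were among the 6 members above control, and with butyrate (-0.17, 16 of 19). Against the mean of the other 3 pools the medians with acetate and butyrate were -0.027 and -0.0010 and no longer stood apart. Pancreatic acinar markers, from a tissue rich in these genes, were lower in the same 3 pools, by medians of -0.74, -0.57 and -0.35.

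NRF2 targets were higher with propionate as with acetate (median 0.27, 11 of 12 above control, above all 10000 random lists), with Slc7a11, below the floor, at 1.05, Gclc at 0.49 and Hmox1 at 0.46. Fatty acid synthesis genes were lower by a small amount, with 13 of 20 below control, none by 1.5-fold, and a median of -0.087 (percentile 0.40). The lipase-family gene Pnpla3 was at -0.34 and the acetyl-CoA carboxylase Acaca at -0.29. That list did not stand apart against the mean of the other 3 pools. Female-biased genes were higher (0.10, percentile 99.3), with Ntrk2, below the floor in both pools, at 0.90 after Cyp2b9. The 7 measured genes known to rise when histone deacetylases are inhibited had a median of 0.15 (percentile 99.3), led by Cdkn1a (0.36) and the linker histone H1f2 (0.34), but did not stand apart with cyclic loess or with members above the floor. Periportal markers had a median of 0.070 (percentile 99.5), led by Aldh1b1 (0.70) and Cdh1 (0.26), and did not stand apart from unmatched random lists.

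Kupffer cell markers were higher with propionate in 12 of 14 cases (median 0.28, above all 10000 random lists), with Marco, Adgre1 (0.72) and Lyz2 (0.68) above 1.5-fold. Stellate cell and fibroblast markers had a median of 0.10 (percentile 99.8), led by Col1a1 (0.55) and Col1a2 (0.51). Skeletal muscle markers were slightly higher (0.15, percentile 99.2), with Tnnt3 at 0.42 and Tnni2 at 0.30, and their mean of 0.092 did not stand apart. Neutrophil and monocyte markers had a median of 0.15 (percentile 97.0), within the range of random lists.

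In the butyrate pool the lowest genes were those of muscle, and Muc2, Lypd8 and Ngp were the highest. The goblet cell mucin Muc2 was 7.89-fold above control and the colon surface protein Lypd8 7.85-fold. Ngp was 6.74-fold higher, the B cell chemokine Cxcl13 3.78-fold and the carbonic anhydrase Car1 3.72-fold. The red cell anion exchanger Slc4a1 (1.34), Marco (1.40), Sprr2a1 (1.27), the interferon-induced chemokine Cxcl9 (1.11), Siglece (1.04), Clec4a3 (1.03) and Clec4a1 (1.01) followed. All of the 12 lowest genes are abundant in muscle. The myosin light chain Myl1 was 8.87-fold below control, myoglobin (Mb) 7.89-fold and the calcium pump Atp2a1 6.85-fold. The others were Tnnt3 (-2.53), Acta1 (-2.48), Myh2 (-2.32), Myh4 (-1.77), Myh1 (-1.47), Tpm2 (-1.47), Cox8b (-1.43), Actn2 (-1.40) and Pygm (-1.21). Mb stood at 7.50, 7.20 and 7.54 in the control, acetate and propionate pools and at 4.52 with butyrate. Muc2 (5.13), Slc4a1 (5.21) and Sprr2a1 (5.46) lay below the floor in the control pool, as did all of the 12 muscle genes except Acta1 in the butyrate pool.

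Skeletal muscle markers had a median of -2.04 with butyrate (below all 10000 random lists), and 10 of 11 were at least 1.5-fold below control. Adipocyte markers were lower too, with 7 of 8 below control and a median of -0.31 (below all 10000 random lists), led by Retn (-1.09) and Adipoq (-0.74), both with mean levels below the floor, as had 4 of the 8 markers. Des, counted among stellate cell markers and also a muscle gene, was at -0.75. Without the genes of the muscle, pancreas, intestine, blood cell and adipocyte lists, 66 genes were higher with butyrate and 23 lower, 58 and 31 with acetate, and 66 and 28 with propionate. That count was added after the data had been seen. Myl1, Myh1, Tpm2, Cox8b, Actn2 and Pygm were in none of these lists and stayed among the lower genes with butyrate. Muc2 and Lypd8 likewise stayed among the higher genes, so the butyrate counts are not free of muscle and gut genes.

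Markers of immune cells were higher with butyrate. All 14 Kupffer cell markers lay above control, 5 by at least 1.5-fold, with a median of 0.55 (above all 10000 random lists). Marco led, followed by Adgre1 (0.76), Cd68 (0.76), Lyz2 (0.75) and Timd4 (0.70). All 12 neutrophil and monocyte markers were above control, 6 by at least 1.5-fold (median 0.57, above all 10000 random lists), with S100a8 at 1.22, Ltf at 1.22 and S100a9 at 0.86. S100a8 and Ltf lay below the floor in control. Interferon response genes had a median of 0.26 (above all 10000 random lists) with 16 of 20 above control, among them Cxcl10 (0.90) and Gbp2 (0.52). Lymphocyte (0.13, percentile 98.5), endothelial (0.10, percentile 99.6) and cholangiocyte markers (0.15, percentile 97.9) stood apart by less. Mean levels at or above the floor were found for 2 of 14 lymphocyte and 2 of 8 cholangiocyte markers, so these calls rest mostly on values near background. Their largest ratios were those of Nkg7 (0.50), Lyve1 (0.67) and Epcam (0.64). Against the mean of the other 3 pools the endothelial and cholangiocyte lists (0.047 and 0.012) no longer stood apart, nor did cholangiocyte markers by their mean.

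Cholesterol synthesis genes were lower with butyrate in 19 of 20 cases, none by 1.5-fold, with a median of -0.20 (below all 10000 random lists). The largest ratios were those of farnesyl diphosphate synthase Fdps (-0.56), Nsdhl (-0.37), Cyp51 (-0.36), Idi1 (-0.35) and Sqle (-0.33). With acetate and propionate the medians of the same list were 0.010 (mean -0.019) and -0.0039, within the range of random lists. Fatty acid synthesis genes were lower as well, with 16 of 20 below control and a median of -0.12 (below all 10000 random lists). Thrsp was at -0.51, the acetyl-CoA synthetase Acss2, which activates acetate, at -0.50, Pnpla3 at -0.40 and the lipogenic regulator Srebf1 at -0.32.

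Other lists differed by little with butyrate. Fatty acid oxidation (0.055, percentile 98.5), xenobiotic metabolism (0.067, percentile 98.3) and female-biased genes (0.085, percentile 98.1) were higher, and each call ended with the list's mean and against unmatched random lists. The largest ratios among oxidation genes were those of Etfdh (0.16) and Acaa1b (0.13), among xenobiotic genes Abcb1a (0.47) and Cyp2c38 (0.42), and among female-biased genes Hao2 (0.42) and Cyp2b9 (-0.41). Abcb1a lay below the floor in control, and Hao2 and Cyp2b9 in both pools. The xenobiotic list had medians of 0.021 and -0.059 with acetate and propionate, where Cyp2b10 stood at 1.60 and 0.17, near background in the control pool. PPARalpha targets had a median of 0.045 and a mean of -0.081 with butyrate and did not stand apart. The lowest ratios in the list were those of Fabp3 (-1.94), a gene abundant in muscle and below the floor with butyrate, and Pdk4 (-0.72). The 4 measured red cell genes were too few for a percentile, and with butyrate Car1 and Slc4a1 were higher while Epb42 stood at 0.15 and Alas2 at 0.14. Epb42 lay below the floor in all pools. The medians of these 4 were -0.14, 0.13 and 0.74 with acetate, propionate and butyrate.

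**Figure D1:**
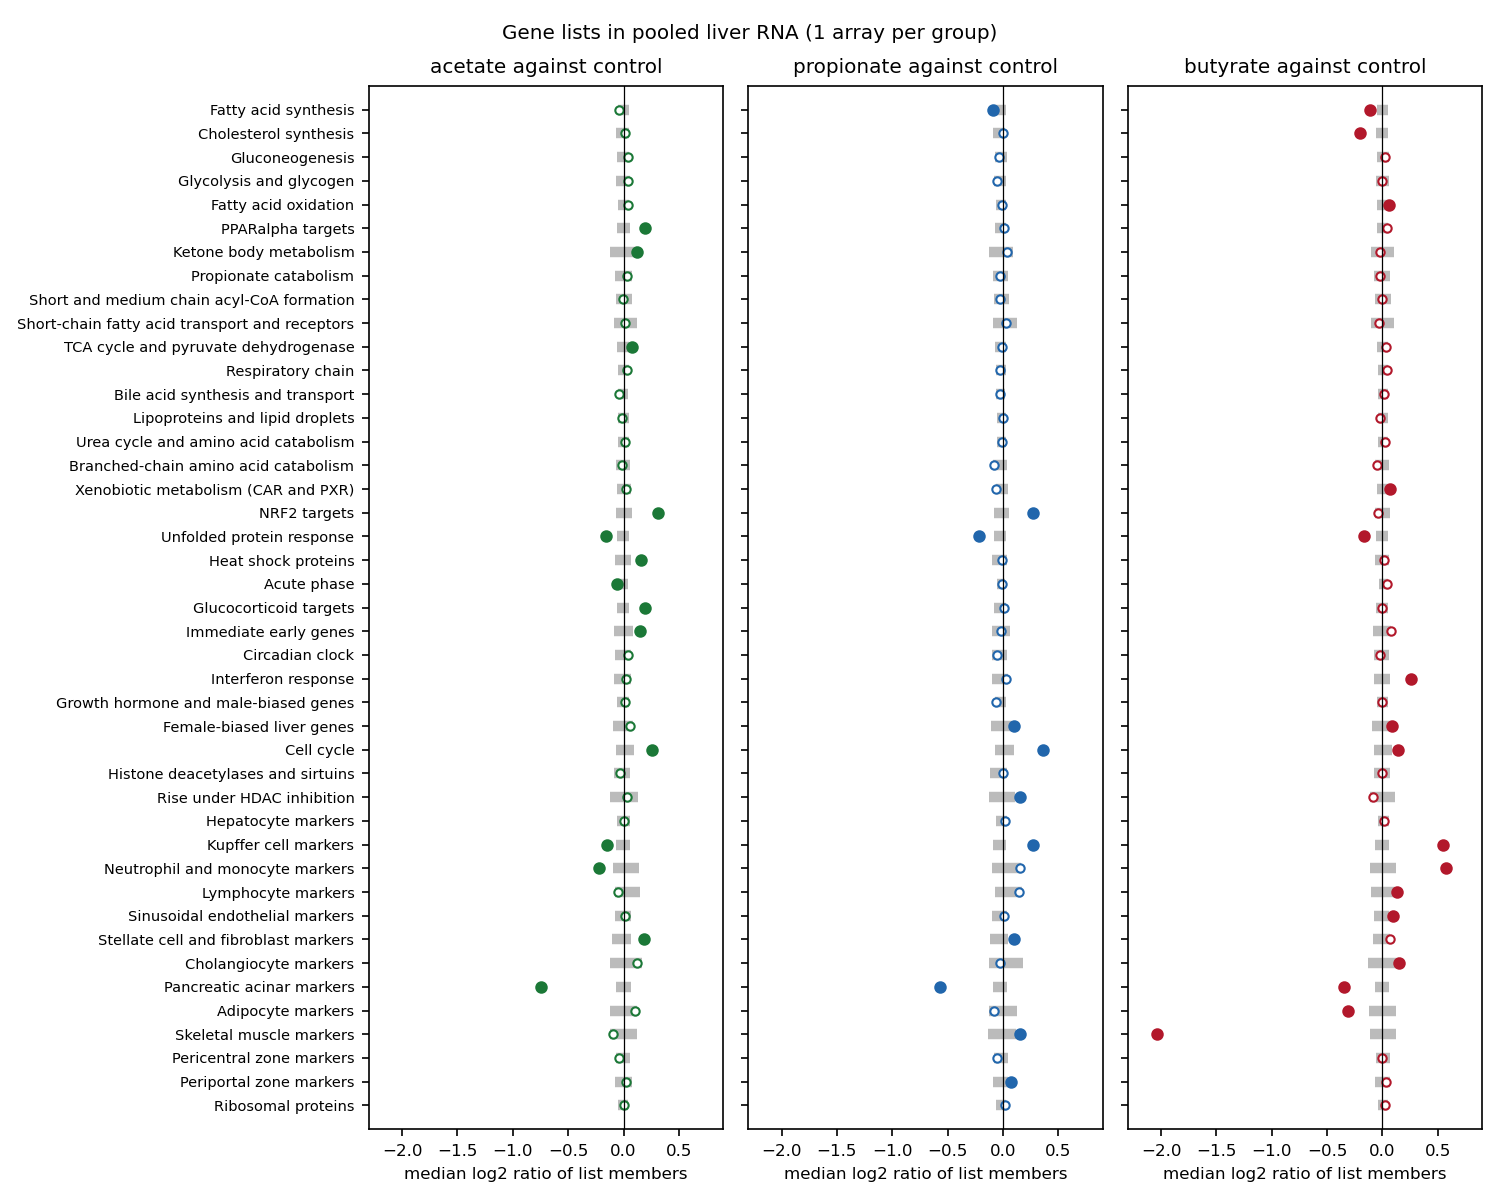
Median log2 ratio to the control pool (horizontal axis) of the 43 fixed gene lists with at least 5 measured members, for acetate, propionate and butyrate, 1 array per group. Grey bars span the central 95% of 10000 matched random lists, and filled points lie outside it; skeletal muscle markers lie at -2.04 with butyrate and Kupffer cell markers at -0.15, 0.28 and 0.55 with the 3 acids.

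Cell cycle genes were higher with all 3 acids. With acetate 17 of 22 members were above control, 6 by at least 1.5-fold (median 0.26), with propionate 20 and 7 (median 0.36), and with butyrate 18 and 2 (median 0.14). These medians lay at percentile 99.99 with acetate, above all 10000 random lists with propionate and at percentile 99.95 with butyrate. Mki67, a marker of proliferating cells, was at 0.97, 0.86 and 0.87 and Ccna2 at 0.86, 0.79 and 0.73, both from levels below the floor in the control pool. For butyrate the list did not stand apart with members above the floor, and against the mean of the other 3 pools its median was -0.029. The median level of the list was 5.13 in control and 5.42, 5.51 and 5.37 with acetate, propionate and butyrate, below the floor. For the part shared by all 3 acids, a low value of the single control pool and an effect of the infusions cannot be told apart.

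Mki67 and Ccna2 were the 2 genes at least 1.5-fold higher with all 3 acids, and Ppy, Sdf2l1 and Tff2 the 3 that were lower. The next on the higher side were Gucy2c, Erdr1 (0.75, 0.48 and 0.88), the interferon-induced Usp18 (0.68, 0.46 and 0.45), Marcksl1, Cd72 and Cd63. Gucy2c and Cd63 lay below the floor in control, Tff2 with acetate and Ppy with all 3 acids. On the lower side they were the pancreatic genes Cela3b, Rnase1, Cpa1 and Clps, and Zfp931. Pancreatic acinar markers were below control in 13, 12 and 13 of 13 cases with acetate, propionate and butyrate, 9, 6 and 0 of them by at least 1.5-fold. Their levels were high in all 4 pools, with Cpa1 at 11.61 in control and 11.04, 11.09 and 11.15 with the acids. Against the mean of the other 3 pools the acinar median with butyrate was 0.048.

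Because the acids shared the control pool, their ratios are related without any effect. Across genes the correlation of log2 ratios was 0.64 for acetate and propionate, 0.24 for acetate and butyrate and 0.38 for propionate and butyrate, where simulated unchanged groups gave 0.50. The simulated correlation follows from giving each group equal noise. The covariances were 0.0196, 0.00817 and 0.0125 against a simulated 0.0112. The difference was 0.00842 for acetate and propionate, -0.00304 for acetate and butyrate and 0.00133 for propionate and butyrate. The simulated noise came from propionate against acetate, with an SD of ratios of 0.15. That SD was 0.23 for butyrate against acetate and 0.20 for butyrate against propionate. Wider noise would raise the simulated covariance and the simulated calls below, so the sign and size of these differences depend on that choice. For acetate and propionate the noise came from the ratio of that same pair. Their difference in covariance restates that their SDs against control, 0.18 and 0.17, exceeded the 0.15 of the direct ratio. It is no test of a shared effect. Simulated unchanged groups shared 0.34 calls of either direction. Acetate and propionate had 23 higher and 16 lower genes in common and none in opposite directions. Independent lists would share 0.414 and 0.194. Acetate and butyrate shared 4 higher and 5 lower genes (0.445 and 0.173 if independent), with 3 in opposite directions. Propionate and butyrate shared 23 higher and 4 lower genes (0.498 and 0.137 if independent). With 1 control array the control could not be split, and part of each excess may come from it.

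**Figure D2:**
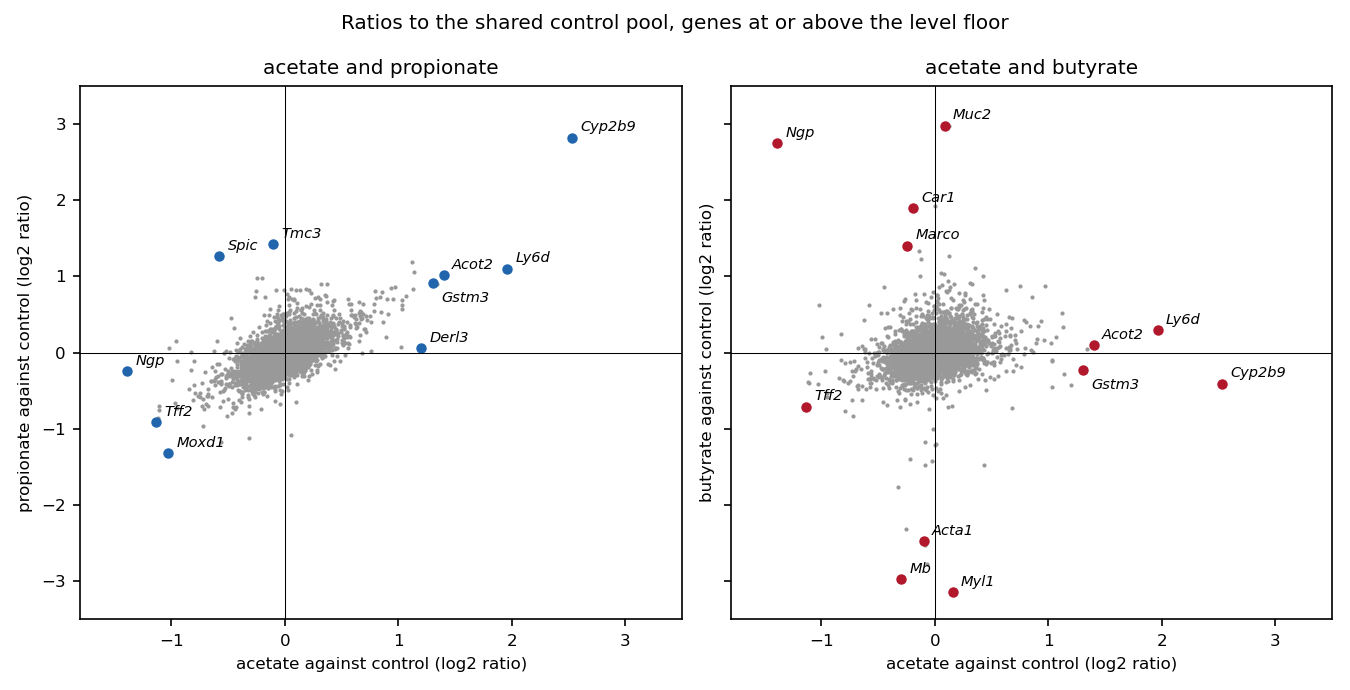
Log2 ratio to the shared control pool of each gene at or above the level floor, for acetate (horizontal axis) against propionate (left) and butyrate (right), 1 array per group. Coloured points are named genes; Cyp2b9 lies at 2.53 with acetate, 2.82 with propionate and -0.41 with butyrate.

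The acids were next compared with one another at the same dose and time, without the control. With 1 pool each there was no test or interval for these differences. Propionate and acetate were the closest by gene counts, with 39 genes at least 1.5-fold higher with propionate and 13 lower. Spic (1.85), Tmc3 (1.53), Marco (1.22), Clec4n (1.18), Ngp (2.21-fold) and Orm2 (1.11) were the highest. Ngp lay below the floor in both pools and Tmc3 in the acetate pool. Derl3 (-1.14), Btbd19 (-1.14), the immediate early gene Nr4a1 (-0.96), Ly6d (-0.86), Dmbt1 (-0.81) and Cabyr (-0.75) were the lowest. Lists that stood apart numbered 18, against 16 for butyrate against acetate and 14 for butyrate against propionate, so by lists this pair was not the closest. Higher with propionate were markers of Kupffer cells (0.22, 14 of 14 members), neutrophils and monocytes (0.30), lymphocytes (0.12), muscle (0.31) and pancreatic acini (0.18), and acute-phase (0.051), female-biased (0.10) and cell cycle genes (0.090). Lower were adipocyte (-0.35), cholangiocyte (-0.17) and stellate cell markers (-0.10), and genes of the immediate early (-0.17), heat shock (-0.13), unfolded protein (-0.13) and glucocorticoid response (-0.11), the male-biased genes (-0.084), xenobiotic metabolism (-0.075) and the TCA cycle (-0.071). The cell cycle median turned to -0.067 with members above the floor, where the xenobiotic list was at -0.018 and no longer apart. By their means the cell cycle and female-biased lists did not stand apart, and against unmatched random lists the TCA cycle, xenobiotic, acute-phase and male-biased lists did not.

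Butyrate and acetate were the farthest apart, with 99 genes higher with butyrate and 80 lower. Ngp was 17.7-fold higher with butyrate, Muc2 7.44-fold and Lypd8 7.20-fold, followed by Car1 (2.09), Cxcl13 (1.92) and Marco (1.65). Ngp and Muc2 lay below the floor in the acetate pool, at 4.40 and 5.22, so their folds are not exact. Next to Myl1, Atp2a1, Mb, Tnnt3 and Acta1 (-3.31 to -2.38), Cyp2b9 was among the 6 lowest (-2.94), of which all but Acta1 lay below the floor with butyrate. NRF2 targets were lower with butyrate than with acetate, in 10 of 12 cases (median -0.28, below all 10000 random lists), as were PPARalpha targets (-0.16), cholesterol (-0.17) and fatty acid synthesis (-0.11), heat shock (-0.20), glucocorticoid (-0.088) and immediate early genes (-0.17), and stellate cell (-0.27), adipocyte (-0.54) and muscle markers (-1.76). Higher were Kupffer cell (0.50), neutrophil and monocyte (0.66), lymphocyte (0.12) and acinar markers (0.37), interferon (0.18) and acute-phase genes (0.12). Glucocorticoid targets did not stand apart from unmatched random lists.

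Between butyrate and propionate, 33 genes were higher with butyrate and 57 lower. With quantile normalization on top the split was 23 and 64, a share of higher genes of 26.4% in place of 36.7%. Muc2 (3.20), Lypd8 (3.13), Ngp (8.01-fold), Car1 (2.30), Cxcl13 (1.42) and Sprr2a1 (1.27) were the highest. Myl1, Mb, Atp2a1, Tnnt3 and Acta1 (-3.30 to -2.69) and Cyp2b9 (-3.23) were the lowest. Muc2, Lypd8, Ngp and Sprr2a1 lay below the floor in the propionate pool, and the 6 lowest except Acta1 in the butyrate pool. Lower with butyrate were NRF2 targets (-0.23), cell cycle (-0.21), cholesterol (-0.21) and fatty acid synthesis genes (-0.059), and stellate cell (-0.17), adipocyte (-0.19) and muscle markers (-1.92). Higher were interferon (0.22), unfolded protein response (0.12) and xenobiotic genes (0.13), and Kupffer cell (0.22), neutrophil and monocyte (0.30), lymphocyte (0.13) and acinar markers (0.16). Fatty acid synthesis did not stand apart from unmatched random lists, nor did neutrophil and monocyte markers with members above the floor (0.19) or lymphocyte markers by their mean (0.048).

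**Figure D3:**
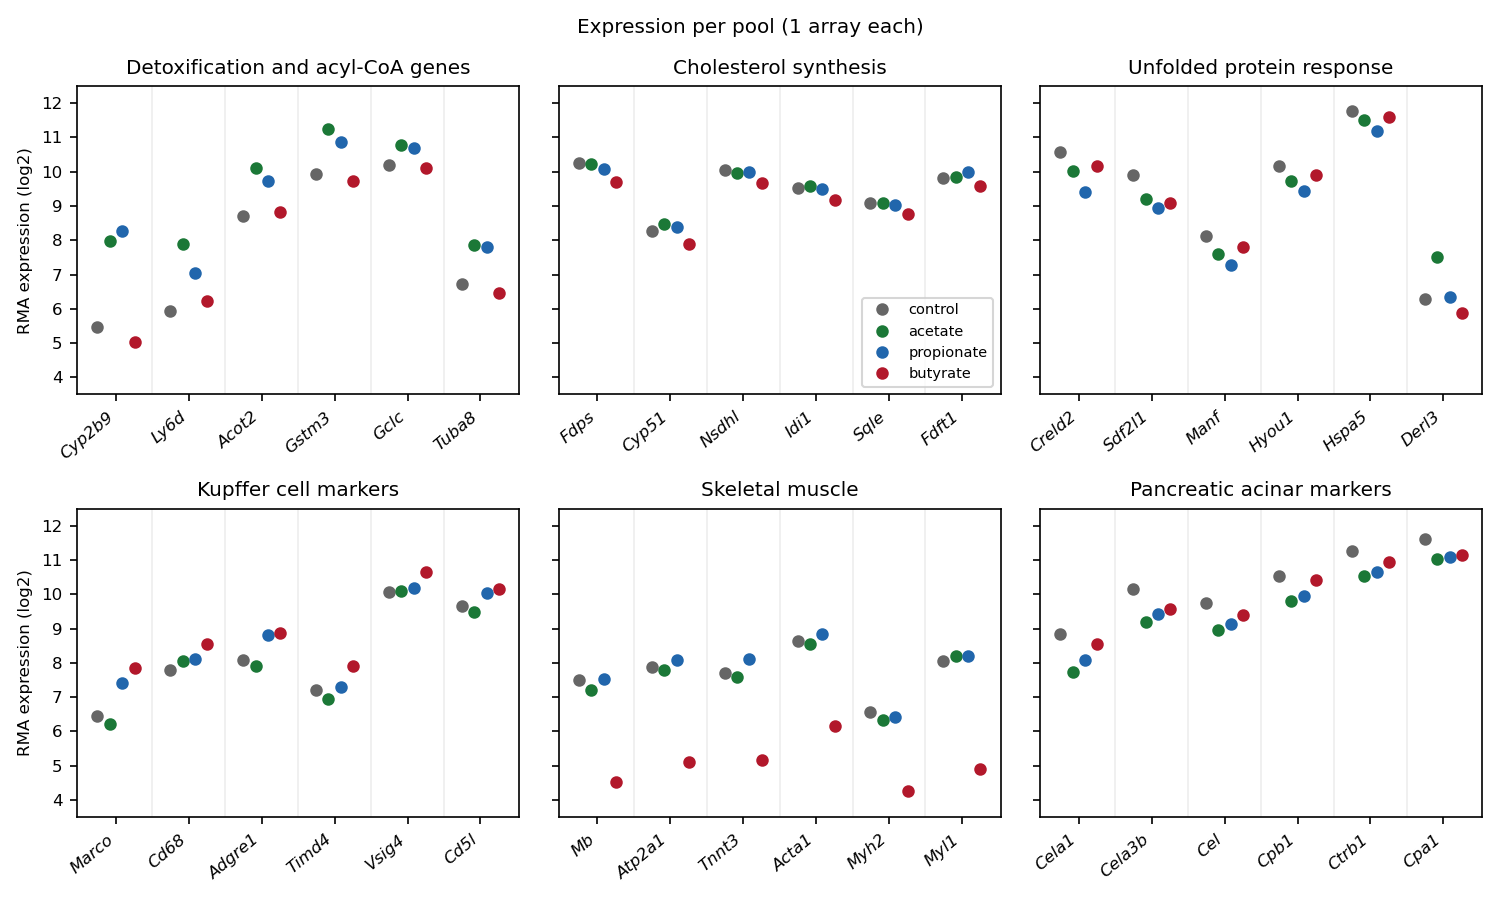
RMA expression (log2, vertical axis) of named genes in the control, acetate, propionate and butyrate pools, 1 point per array. Acot2 stands at 8.71, 10.11, 9.73 and 8.81 in that order, and Fdps at 10.24, 10.23, 10.08 and 9.69.

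Several lists close to the study's subject did not stand apart with any acid against control. Medians over the 3 acids ran from -0.035 to 0.037 for gluconeogenesis, -0.058 to 0.041 for glycolysis and glycogen, -0.031 to 0.034 for propionate catabolism, -0.030 to -0.0030 for acyl-CoA formation, -0.035 to 0.026 for short-chain fatty acid transport and receptors and -0.025 to 0.045 for the respiratory chain. The gluconeogenic genes Pck1 (-0.020, 0.036 and 0.0057) and G6pc (0.037, -0.072 and 0.16) hardly differed with acetate, propionate and butyrate, and the coactivator Ppargc1a stood at 0.51, 0.13 and 0.22. The lipogenic enzyme Fasn stood at -0.081, -0.20 and -0.22, the oxidation gatekeeper Cpt1a at -0.10, -0.033 and 0.093 and Fgf21 at 0.19, -0.069 and 0.069. The receptors Ffar2 and Ffar3 had levels of 4.75 and 3.52 in control, below the floor.

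Medians ran from -0.040 to 0.018 for bile acid genes, -0.018 to 0.0014 for lipoproteins and lipid droplets, -0.011 to 0.025 for the urea cycle, -0.085 to -0.017 for branched-chain amino acids, -0.050 to 0.043 for the circadian clock, -0.064 to 0.010 for growth hormone and male-biased genes, -0.027 to 0.0031 for histone deacetylases and sirtuins, -0.053 to -0.0049 for pericentral markers, 0.0031 to 0.015 for hepatocyte markers and 0.0053 to 0.027 for ribosomal proteins. With at least 1 acid the median and the mean differed in sign, both near 0, for glycolysis and glycogen, the respiratory chain, lipoproteins and lipid droplets, histone deacetylases and sirtuins, hepatocyte markers and ribosomal proteins. Within the bile acid list, Cyp7a1, the rate-limiting enzyme of bile acid synthesis, was 1.56-fold below control with acetate and Cyp8b1 1.54-fold. Their log2 ratios were -0.19 and 0.017 with propionate and 0.082 and 0.42 with butyrate. No histone deacetylase gene differed by 1.5-fold, and Hdac9 (0.37 with butyrate) had the largest ratio.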

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

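The tests of an array-wide fault, of red cell RNA, of pancreas RNA and of the control pool were chosen after the results had been seen; those on further muscle and intestinal genes were set before those genes' values were looked at, except for Krt7, Krt19 and Pigr, and the repeat without these 3 was added after.

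Some marker lists stood on opposite sides of the control pool with different acids. The median of Kupffer cell markers was higher with propionate than with acetate by 0.42 and with butyrate than with acetate by 0.70, as differences of their medians to control. For neutrophil and monocyte markers butyrate lay above acetate by 0.79. For skeletal muscle markers the difference of butyrate from propionate was -2.19. The direct medians between these acids were smaller, at 0.22, 0.50, 0.66 and -1.92 in the same order. The side of Kupffer cell markers with acetate rested on the median, since their mean of -0.053 did not stand apart (6 members above control and 8 below), and so did that of muscle markers with propionate (mean 0.092). With 1 pool per group these differences were not tested.

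Muscle genes were lower in the butyrate pool alone. A fault of that whole array was not seen at background level. There the genes of families not used by liver had a spread against control of 0.988 times the mean of the other acids. Such genes cannot show a fault that acts on expressed genes. At or above the floor the SD of ratios to control was 0.18, 0.17 and 0.19 with acetate, propionate and butyrate. The shares of genes within 1.2-fold were 90.1%, 89.8% and 91.4%, so a fault stays open. A candidate explanation is less skeletal muscle RNA in this pool than in the other 3. Of 30 further muscle genes, 29 lay below control (median -0.59, below all 10000 random lists), but 4 of the 30 reached the level floor, and the median of these 4 as a log2 ratio to the mean of the other 3 pools was -0.58 (from -0.86 to -0.45), between the bounds set beforehand of -1 and -0.5. The median level of the 30 genes was 5.00 in control and 4.14 with butyrate, below the floor, where background compresses ratios. That left 4 genes for the test, which could not decide. Both a smaller share of muscle RNA and an effect of butyrate in muscle cells place muscle RNA in the other 3 pools. These 2 readings cannot be told apart here, and no sample of muscle was measured.

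Muc2, Lypd8 and Car1 were higher in the butyrate pool alone. Red cells as the source of Car1 stay open, since Alas2 was at 0.14 while Slc4a1, below the level floor in the control pool, was at 1.34. Intestinal epithelium RNA may have entered the pool: 40 further intestinal genes had a median of 0.059 over the mean of the other 3 pools (percentile 99.6, 26 higher, 5 by at least 1.5-fold), among them Muc3 (2.14 against control), Muc13 (1.46) and Mptx1 (1.34). Of these 40 genes 8 lay at or above the floor, 3 (Krt7, Krt19 and Pigr) belong to lists already examined (without them the median was 0.055, percentile 99.25), and some genes abundant in that epithelium differed little, such as Krt19 (0.25), Phgr1 (0.27) and Cldn3 (-0.0095). An effect of butyrate on liver cells stays open and was not tested.

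Unfolded protein response genes were lower with all 3 acids. Less pancreas RNA in the acid pools is argued against as the whole cause, because the list was lower with propionate than with acetate (-0.13) while acinar markers were higher (0.18). That control lay 0.13 above the mean of the acid pools restates the pattern and decides nothing. A high value of the single control pool and an effect of every infused acid, or of sodium, cannot be told apart with 1 control array.

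Probe sets outside the gene comparisons also held values at least 1.5-fold above control. Among 835 probe sets with several gene symbols at or above the floor these were 8 with acetate, 8 with propionate and 7 with butyrate, and 2, 2 and 1 were lower by as much. Their largest ratios were 9.91-fold, 5.12-fold and 4.74-fold above control. With acetate that exceeded the largest ratio of the counted genes, 5.79-fold. Among 3980 with no symbol 76, 65 and 119 were higher and 121, 150 and 103 lower, together 4.95%, 5.40% and 5.58%, against 1.14%, 1.11% and 1.12% of named genes.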

How the results depend on the processing

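The count without foreign-tissue lists was chosen after the data had been seen, and the other alternatives before the data were examined. Cyclic loess, quantile normalization and the highest probe set per symbol kept all 12 counts of genes within 1.5 times. The counts depended on the size rule and the floor by construction, since these change which genes can be counted. Counts are given as higher and lower for acetate, propionate and butyrate against control, then propionate against acetate, butyrate against acetate and butyrate against propionate. At 1.3-fold they were 180 and 161, 200 and 179, 211 and 115, 143 and 93, 281 and 245, and 212 and 179. At 2-fold they were 14 and 7, 7 and 4, 14 and 15, 9 and 2, 18 and 25, and 6 and 20. With no floor they were 131 and 93, 146 and 92, 137 and 116, 72 and 40, 172 and 180, and 80 and 159. With a floor at the upper quartile they were 12 and 23, 16 and 18, 21 and 6, 9 and 5, 31 and 13, and 7 and 8. Against the mean of the other 3 pools, which holds part of the acids' own differences, 32 genes were higher with acetate, 31 with propionate and 40 with butyrate, and 11 were lower with propionate. Without the muscle, pancreas, intestine, blood cell and adipocyte lists, 31 were lower with acetate. Of 89 lists that stood apart over the 6 comparisons, 86 did so with cyclic loess, 79 with the mean of the list and 76 against unmatched random lists. With members above the floor it was 72 of 79, and against the mean of the other 3 pools 32 of 41. Among those that did not, 3 turned: cell cycle genes with butyrate (-0.029) and acinar markers with butyrate (0.048), both against the mean of the other 3 pools, and cell cycle genes for propionate against acetate with members above the floor (-0.067). The cause was not tested. All 108 ratios of named genes against control or between acids kept within the background spread with cyclic loess, and against the mean of the other 3 pools 46 of 72 moved by more, none in sign. No paired analysis was possible because each group holds 1 sample. Low signal limits genes near the floor, where background compresses ratios.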

Other observations

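Gene families defined by their symbols were examined after the data had been seen, 23 in all. For lists of random genes 1.15 would lie outside the range per comparison. That number does not hold for families chosen after the data had been seen, some with genes already ranked high, such as Tuba8 and Gstm3. Whether the counts that follow exceed chance can therefore not be judged. Against control, 9 stood apart with acetate, 7 with propionate and 8 with butyrate, all higher except 1 with acetate, the translation initiation factors (-0.057, percentile 0.58). MHC class II genes and Cd74, which present antigen, were higher with all 3 acids, by medians of 0.17, 0.39 and 0.37 over 7 genes. Kupffer cell markers had medians of -0.15, 0.28 and 0.55 in the same pools, and neutrophil and monocyte markers -0.22, 0.15 and 0.57. Chemokines also stood apart with all 3 acids (0.11, 0.079 and 0.16), with 0, 5 and 6 of 32 genes at least 1.5-fold higher, but their median level of 4.72 in control lay below the level floor. Interferon-inducible GTPases were higher with butyrate in all 9 cases (median 0.32), where the macrophage, neutrophil and monocyte markers were higher too, against -0.025 with acetate and 0.0052 with propionate. Toll-like receptors had a median of 0.15 with butyrate (percentile 99.4).

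Tubulins were higher with acetate (0.14, percentile 99.8) and propionate (0.18, percentile 99.99), led by Tuba8, and stood at -0.080 with butyrate. Collagens (0.092, 0.16 and 0.029) and UDP-glucuronosyltransferases (0.10, 0.12 and 0.054) stood apart with the same pair of acids. Stellate cell and fibroblast markers, which share Col1a1, Col1a2 and Col3a1 with the collagens, had medians of 0.18, 0.10 and 0.065, and the collagens' median level of 4.98 in control lay below the floor. For tubulins, collagens and UDP-glucuronosyltransferases the butyrate median lay within the range of random lists. Major urinary proteins were higher with butyrate in all 5 measured cases (median 0.15), although these genes are near-identical in sequence and can share signal on an array. Pancreatic endocrine and ductal genes, a list partly chosen from values already seen, had medians of -0.22, -0.18 and -0.20.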
